A study of Drosophila melanogaster with 62 samples.

How the data were processed

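Poly(A) RNA from pooled male Drosophila melanogaster embryos was sequenced as stranded libraries, per the labels' protocols. The 58 embryo libraries cover an early window of 14 to 16 h and a late window of 18 to 22 h, in wild type and in mutants of the 3 paralogous RNA-binding protein genes elav, fne and Rbp9. A further 2 libraries are RNA from wild-type adult heads, and 2 are iCLIP libraries of ELAV from adult heads, which are not analysed here. Groups, stages and experiments were taken from the labels. Of the labels, those of the 3 fne-rbp9 libraries give the late window but name an early table. That table is used as deposited. The titles of the fne-rbp9 libraries do not give 18 to 22 h, which every late title of the first experiment gives. Because the labels conflict, the stage of these libraries is treated as unclear. Nothing in the labels says whether replicates came from separate crosses or collections, so the authors' p-values measure the spread between these libraries, which may be technical. The tests made here run over genes, and their p-values do not measure the spread between libraries.

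The authors deposited their own comparisons for the embryos, and no values per library were used here. Each of the 10 tables of the first experiment sets a mutant against wild type of the same stage and holds 1 row per gene for a segment, or several segments, of the gene. Of the 224 entries with several segments, 22 had other sequence between them. The log2 fold of segment use, mutant over wild type, is the authors' value, with a p-value and an adjusted p-value per row, per the file headers. Other columns hold a fitted use score for each condition, a dispersion and a mean normalised count, per the file headers. The column names are those of a differential exon use test, but the tool, its version and its settings are not given in the sources used here. Every row has an adjusted p under 0.0001 and a log2 fold of -0.75 or lower, as tested on the files, so these tables are lists of decreases and the absence of increases in them carries no information. The 4 tables of the second experiment hold 1 weighted log2 fold and the smallest adjusted p-value over a gene's segments, per the file headers, for 174 genes in each. Those genes and segments are the same in all 4 tables and all come from the elav early list of the first experiment. A smallest p over several segments passes a threshold more easily than a single p. The authors' 2 segment annotations, made with rtracklayer 1.40.5 per the file headers, are in dm6 coordinates, per the submitters' processing notes. Segment type codes such as TE and LE are not defined in the sources used here and are quoted as codes. Head expression is in TPM, as the authors deposited it. The 17753 listed genes sum to 360087 TPM in replicate 1 and 365410 TPM in replicate 2, so part of each total is not listed.

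Tables were fitted separately by the authors. Fold differences between tables therefore compare 2 fits, gene by gene. They were tested with a two-sided sign-flip permutation test of the mean difference over genes in both tables, with 100000 resamples, and with all sign assignments below 10 genes. The smallest p that 100000 resamples can give is 1e-05, which became 1.3e-05 after adjustment. Overlaps of lists were tested with a two-sided Fisher's exact test against genes with at least 2 segments in the authors' annotation, 12624 early and 12625 late. The expected overlap of independent lists was taken as the product of the list sizes over the background. Comparisons of 1 stage share their wild-type libraries, so their lists overlap in part by chance, and without values per library this part could not be simulated. Lists of early and late embryos share no library. Enrichment of 14 gene lists was tested in the same way. The split of folds in the second experiment was tested with a two-sided exact binomial test. Head expression on the log2(TPM + 1) scale and log2 summed segment length were compared between listed genes and other genes with a two-sided permutation test of 100000 resamples. Benjamini-Hochberg adjustment was made within each family of tests. Genes are not independent replicates, and these tests describe these gene sets. Only the authors' adjusted p-values were used, and counts adjusted over the list alone were not computed. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. Named segments were placed on the BDGP6.54 annotation of Ensembl release 115, which has the same assembly and chromosome names. All 161 named segments lay in their gene on the same strand, and 152 had at least 90% of their listed bases in an annotated 3′ UTR.

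The tests were tested on simulated data. With the 157 genes of the elav-fne and elav comparison, the sign-flip test called 3.25% of 400 simulations with no shift and 100% with a shift of 0.5 log2. Over 12625 genes, the overlap test called 0.5% of independent lists, and the expression test called 5.75% of random sets. These simulations drew genes independently, and those of the sign-flip test cut back the most extreme differences. They hold neither shared wild-type libraries nor correlated genes, so their rates need not hold for the real tables.

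Before the data were examined, the design, the gene lists, the alternatives and the rule for naming genes were fixed. For each table the rule names the 10 genes with the largest absolute change (all genes where a table holds fewer than 20), the ELAV family, and at most 20 listed members of the fixed lists. For heads it names the ELAV family and the 2 most abundant members of each list. A gene named in 1 table may be set beside its value in another, whatever its rank there. SelR outside the rbp9 and fne late tables, HIP-R, Mhc, apolpp, eEF1alpha1, nSyb, Rop, Rbp, tau and Antp were named after their values were seen. The tests of segment width, of first 3′ UTR segments and of the X chromosome, and the background of genes with at least 2 segments marked as 3′ UTR, were also chosen after the data were seen. Of the 278 list symbols, 274 were matched to an identifier. Alternatives covered stricter thresholds, segments in place of genes, other backgrounds, medians, identical segments, other pseudocounts, a filter at 1 TPM, and each head replicate left out. A planned fit of values per library was not made, because the comparison tables hold none. The depth of each embryo library is therefore unknown, and the fold values carry no standard error.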

Results

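The series measured the use of 3′ UTR segments in Drosophila melanogaster embryos that lack members of the ELAV family. ELAV, FNE and RBP9 are neuronal RNA-binding proteins, and ELAV is known to promote long 3′ UTRs in neurons through alternative polyadenylation, the choice between cleavage sites of a transcript. In the first experiment, early embryos (14 to 16 h) comprised 3 libraries each of wild type, elav, fne, rbp9, elav-rbp9, elav-fne and elav-fne-rbp9. Late embryos (18 to 22 h) comprised 4 wild-type, 3 elav, 4 fne and 5 elav-fne libraries. A set of 3 fne-rbp9 libraries is labelled late but belongs to an early table, so its stage is unclear. The second experiment had 3 libraries each of wild type, nFne and elav-nFne at both stages. From what is known of the study, nFne refers to a form of FNE that enters the nucleus, and the question is whether FNE takes over ELAV's role when ELAV is missing. Values are the authors' log2 folds of relative segment use, mutant over wild type, and a negative fold means that a mutant used the segment less. Depth per embryo library is unknown. As a guide to precision, the median normalised count at listed segments in the authors' deposited table was 164.4 for elav early, 105.1 for elav-fne early, 93.7 for elav late and 75.02 for elav-fne late. Each median is over a different list. A count averaged over mutant and wild type also falls where the mutant uses the segment less, so it does not measure depth alone.

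Early elav embryos used 3′ UTR segments of 185 listed genes less than wild type. The folds of the mutated genes come first, although the relative use of a 3′ UTR segment does not check a mutant label. In the authors' deposited table for elav early, elav itself (FBgn0260400) fell by 2.68 on the log2 scale, at a segment spanning X:509880–513105, all in annotated 3′ UTR. The same table gave fne (FBgn0086675) a log2 fold of -4.13, although that gene was intact. Transcription factors were among the strongest decreases, with log2 folds of -5.79 for ct (the homeodomain protein Cut) and -3.42 for hth (Homothorax, a cofactor of Hox proteins) in the authors' deposited table. The largest decrease there was -5.83, for CG43759. That gene was also listed in elav-rbp9 early (-6.47) and elav late (-3.26) in the authors' deposited tables. It was not listed in elav-fne or elav-fne-rbp9, and its -0.89 in elav-nFne early did not pass (adjusted p = 0.14), in the authors' deposited tables. RNA regulators fell too, with -4.02 for the translational repressor pum, -2.63 for Imp and -2.38 for sm, all from the authors' deposited table. The median log2 fold of the elav early list was -1.41, and 145 of its 185 genes had at least a halving of segment use. The listed segments together had a median width of 1630 bases, 153 of the 185 were coded TE by the authors, and 131 included the last segment of the gene.

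**Figure D1:**
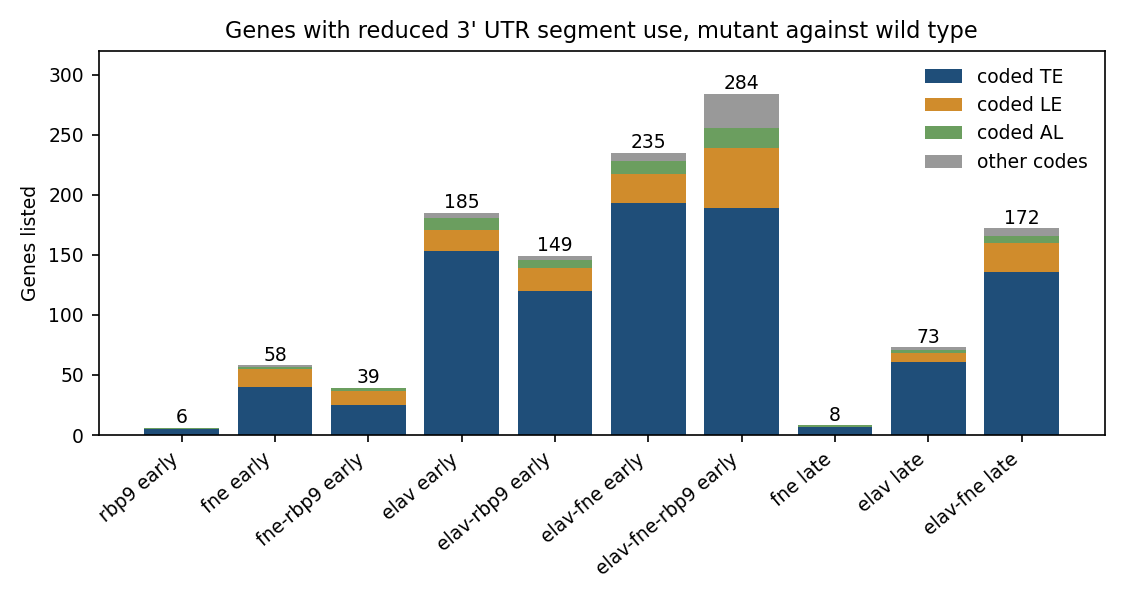
Number of genes listed by the authors as lower in each mutant than in wild type (vertical axis, genes), split by the authors' segment type code. The early lists run from 6 genes in rbp9 to 284 in elav-fne-rbp9, and the late lists hold 8, 73 and 172 genes.

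Loss of fne or Rbp9 alone changed far fewer listed genes than loss of elav. The fne early list held 58 genes, and the largest decrease in the authors' deposited table was at fne itself, with a log2 fold of -8.47. It was followed by fon (-3.91), RhoU (-3.88), ssx (-2.98, a paralog of Sex-lethal) and Fur2 (-2.48) in the same authors' deposited table. The metabolic genes Vha26, a proton pump subunit, and Ldh, lactate dehydrogenase, had log2 folds of -2.09 and -2.06 in the authors' deposited table. Of the 58 genes, 19 were also in the elav early list, against 0.85 for independent lists (odds ratio 36.4, adjusted p = 7.2e-21, Fisher's exact test). Against genes with at least 2 segments marked as 3′ UTR, 2.13 would be shared (odds ratio 14.2), and both comparisons share wild-type libraries, which by itself raises the overlap. The 39 genes listed in fne and not in elav had narrower segments, with a median width of 289 bases against 1662 for the 166 genes listed only in elav. That difference, 0.23-fold in mean log2 width, passed a permutation test (p = 1e-05, the smallest 100000 resamples can give). Early rbp9 embryos had 6 genes: rl (the ERK kinase Rolled, -6.56), Rala (-2.33), CG12164 (-1.64), dnc (a cAMP phosphodiesterase, -1.25), SelR (-1.04) and RpL27 (-0.78), as log2 folds in the authors' deposited table. Rbp9 was not among the genes listed in the rbp9 mutant.

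The combined loss of elav and fne gave deeper decreases than the loss of elav alone at the same genes. Among the 157 genes in both early lists, the mean log2 fold was -2.92 in elav-fne and -1.64 in elav, a difference of -1.28 ± 0.16 (SE over 157 genes), and 150 of the 157 were lower in elav-fne (adjusted p = 1.3e-05, sign-flip permutation test). The median difference was -0.69. In the authors' deposited tables for elav and elav-fne, hth went from -3.42 to -7.55, the synaptic vesicle calcium sensor Syt1 from -2.90 to -6.77, and the calcium-activated potassium channel slo from -1.07 to -7.12. The cell adhesion gene Dscam1 went from -1.05 to -3.55 and the kinase gene sgg from -1.38 to -4.12 in the authors' deposited tables. Folds of -19.18 for fne and -18.27 for Sxl in the authors' deposited table go with a fitted use near 0 in the mutant and are model fits, not sizes to be read literally. The elav-fne early list held 235 genes, 78 of them outside the elav list. Rbp9 (FBgn0010263), the remaining paralog, was listed there with a log2 fold of -0.87 in the authors' deposited table (2L:2965391–2968434, annotated 3′ UTR). Its adjusted p in the authors' deposited table was 7.5e-05. The folds refer to identical segments at 135 of the 157 genes, but not at fne. These tables were fitted separately, share wild-type libraries, and genes in both lists were selected on significance in both.

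**Figure D2:**
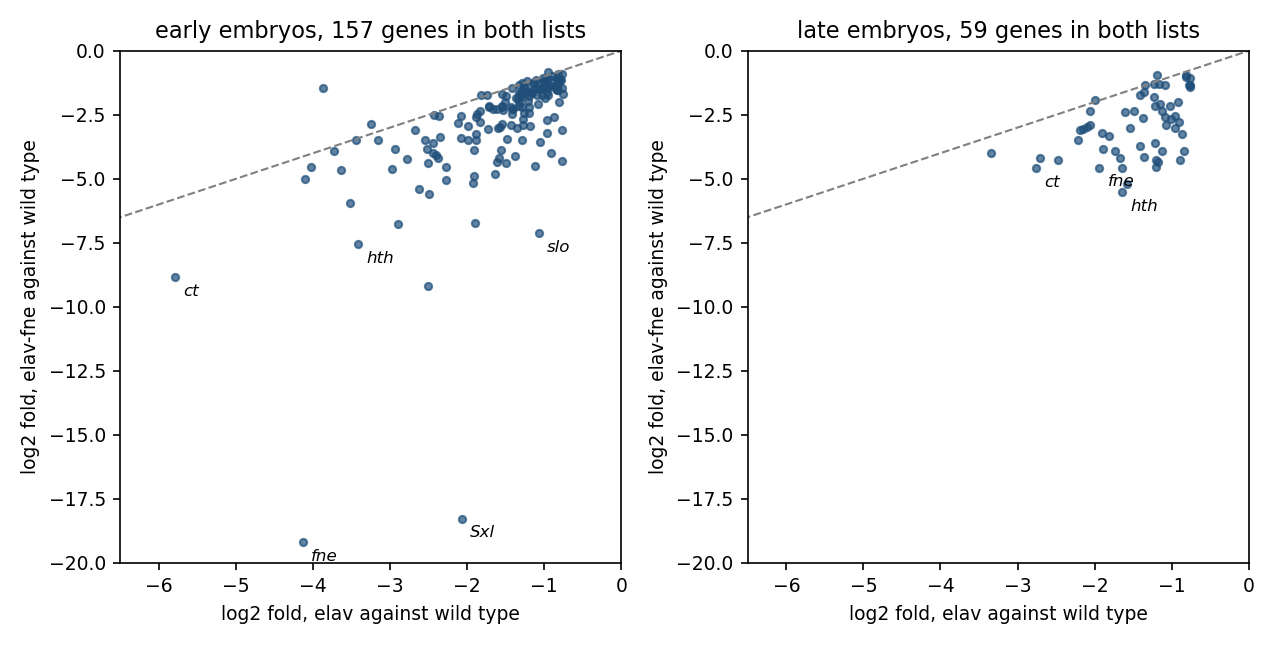
Authors' log2 fold of segment use in elav (horizontal axis) against elav-fne (vertical axis), 1 point per gene in both lists, with a dashed line at equal folds. Of the 157 early genes 150 lie below the line, and of the 59 late genes 56 do.

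The hth locus is an example of where a listed segment lies. That segment, number 26 of the gene, spans 2286 bases at 3R:10507561–10509846 on the minus strand in dm6, all inside the annotated 3′ UTR of hth (FBgn0001235). It is the last segment of the gene and was listed as lower in elav, elav-fne and elav-fne-rbp9 early embryos. The 3 adjoining 3′ UTR segments upstream, numbers 23 to 25, were not listed, but each table holds 1 entry per gene, so this does not show that their use was unchanged. Other named segments lay at 3R:9066343–9067577 for pum (FBgn0003165) and at X:12945778–12950156 for fne in elav-fne early, both wholly in annotated 3′ UTR. In elav early the run of fne segments was shifted by 1 segment. The entry for Syt1 joined 1801 bases, all in annotated 3′ UTR, from separate segments within 2L:2772327–2780740.

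**Figure D3:**
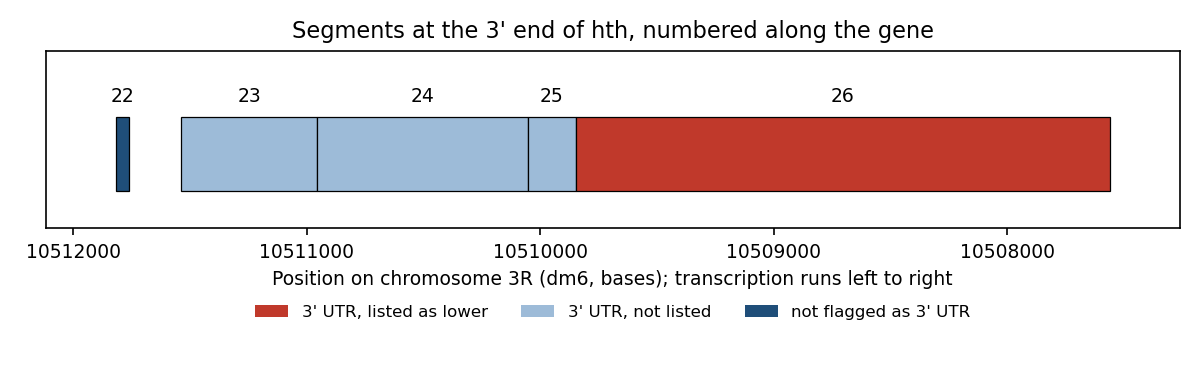
Segments at the 3′ end of hth on chromosome 3R in dm6 (horizontal axis, bases), in the direction of transcription from left to right. The last segment, number 26 (2286 bases), was listed as lower, and segments 23 to 25 of the 3′ UTR were not, in tables that hold 1 entry per gene.

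Adding the loss of Rbp9 had small or mixed effects on the size of the decreases. In elav-rbp9, 149 genes were listed, 136 of them also in elav. Their folds were nearer 0 than in elav by 0.09 ± 0.03 log2 (SE over 136 genes), with 80 of the 136 genes higher (adjusted p = 0.0066, sign-flip permutation test). The median difference was 0.053 and missed the threshold (adjusted p = 0.052, sign-flip permutation test). In elav-fne-rbp9, 284 genes were listed, the most of the 10 lists, and 181 were shared with elav-fne. At these 181 genes the decreases were smaller than in elav-fne by a mean of 0.47 ± 0.11 log2, with 118 genes higher (adjusted p = 1.3e-05, sign-flip permutation test). That mean includes the elav-fne model fits near 0 at fne and Sxl. The median difference was 0.22, and the mean at the 149 genes with identical segments was 0.31. For instance, Syt1 had -4.67, slo -4.20 and hth -6.49 in the authors' deposited table for the triple mutant. These 181 genes were selected on significance in both lists. Counts there were 1.67 times those of elav-fne, and the dispersion 1.21 times (median ratios). With fewer counts a threshold asks for larger elav-fne folds, which may add to the difference. The 103 genes listed in elav-fne-rbp9 and not in elav-fne included rin, tau, Antp and the synaptic genes nSyb, Rop, nwk and Rbp. Not all of the 103 were particular to the triple mutant. In the authors' deposited tables rin had -3.41 in elav early and -3.50 in elav-rbp9, near its -3.59 in the triple mutant. The other named genes were in no other list. Of their 103 segments or runs, 34.0% were marked as the first 3′ UTR segment of the gene, against 6.08% of the 181 shared ones (odds ratio 7.95, p = 2.1e-09, Fisher's exact test). The fne-rbp9 list held 39 genes, 15 of them in the fne list, and the fold difference at those genes was not distinguishable from 0 (-0.82 ± 0.90, p = 0.71, sign-flip permutation test). Its mean and median (0.16) differ in sign, and the mean is 0.066 without fne itself.

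Late embryos gave shorter lists for each mutant sampled at both stages. The late lists held 8 genes in fne, 73 in elav and 172 in elav-fne, against 58, 185 and 235 early. Of the 73 genes in the elav late list, 66 were also in the early one, and of the 172 in the elav-fne late list, 143 were. Folds at shared genes were nearer 0 late, by 0.55 ± 0.10 log2 in elav (50 of 66 genes higher) and by 0.66 ± 0.16 in elav-fne (105 of 143 genes higher), each with adjusted p = 1.3e-05 in the sign-flip permutation test. The elav-fne mean includes the early model fits near 0 at fne and Sxl; its median was 0.29, and the mean at the 67 genes with identical segments was 0.44. Examples from the authors' deposited tables for elav early and late are hth (-3.42 and -1.64) and Syt1 (-2.90 and -1.20), while pum (-4.02 and -3.73) and DIP1 (-3.20 and -4.01) had large decreases at both stages. In the authors' deposited tables DIP1 was not listed in elav-fne at either stage, nor pum in elav-fne late. DIP1 had -0.66 in elav-nFne at both stages without passing (adjusted p = 0.33 early and 0.060 late) in the authors' deposited tables. In elav-rbp9 early DIP1 was listed, with -3.36 in the authors' deposited table. The fne lists shared 5 genes, with a mean of -2.10 late against -3.10 early (exact permutation p = 0.0625, the smallest that 5 genes allow). Only 1 of the 5 had an identical segment at both stages, with a difference of 0.063, so the fne stages could not be compared at like segments. Late elav-fne folds were also set against late elav folds. Among 59 genes in both late lists, elav-fne was lower than elav by a mean of -1.46 ± 0.14 log2, in 56 of 59 genes (adjusted p = 1.3e-05, sign-flip permutation test). Late folds of sm (-1.57 and -5.19) and sgg (-0.84 and -3.92) in the authors' deposited tables for elav and elav-fne are examples. The gene hec, with -16.18 in fne and -15.99 in elav-fne in the authors' deposited tables, has its listed segment 958 bases past that of the mutated gene fne on the X chromosome, on the opposite strand. Those folds, too, go with a fitted use near 0 and are not sizes to be read literally, and whether the fne allele alters hec is not known from these data.

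The second experiment asked the same of the nFne mutant, at 174 genes that the authors had listed in elav early embryos, 173 of which had a fold. These genes were chosen on the first experiment's elav libraries, so they are not a sample of all genes. In early nFne embryos 7 genes passed an adjusted p of 0.05, 5 lower and 2 higher. In early elav-nFne embryos 142 passed, all of them lower. The late numbers were 26 (25 lower, 1 higher) and 156 (all lower). Mean log2 folds over the 173 genes were -0.19 in nFne and -2.13 in elav-nFne early, and -0.45 and -1.71 late. Elav-nFne minus nFne was -1.94 ± 0.09 log2 early (SE over 173 genes), with 171 genes lower, and -1.27 ± 0.08 late, with 163 lower (both adjusted p = 1.3e-05, sign-flip permutation test). Among the largest elav-nFne decreases, the authors' deposited table for early embryos gave hth -6.89, ct -5.47, fne -5.10 and pum -4.94, and that for nFne gave these genes -0.11, -0.09, -0.37 and 0.15. The largest nFne decrease was at chic, which encodes the actin-binding protein profilin, with -3.15 in nFne early and -2.48 in nFne late in the authors' deposited tables. The same gene had -0.83 in elav early, -0.90 in elav-fne early and -1.68 in elav late of the first experiment in the authors' deposited tables. It was not listed in fne early, fne-rbp9 or fne late, so the first experiment did not list it where fne was lost with elav intact. Early nFne embryos had CG30411 at -1.38, CG7556 at -1.36 and Sxl at 0.75 in the authors' deposited table. HIP-R passed with a weighted fold of 0.03 in the authors' deposited table, where the p is the smallest over segments.

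Small nFne shifts pointed one way at most of the fixed genes. In early nFne embryos 78.0% of the 173 folds were negative (exact Clopper-Pearson 95% interval 71.1 to 84.0, adjusted p = 6.1e-14, exact binomial test), and late 95.4% were (91.1 to 97.98, adjusted p = 4.0e-39). In elav-nFne 99.4% were negative early and 98.8% late. All folds of a comparison come from the same 3 mutant and 3 wild-type libraries, so the genes are not independent trials. A shift common to these libraries would move many folds together, which the intervals and p-values do not measure. No segments outside the fixed set were available in this experiment for comparison. An absolute log2 fold of at least 1 left 4 genes in nFne early, all lower, which cannot pass (adjusted p = 0.125, exact binomial test). From early to late, nFne folds moved down by a mean of -0.26 ± 0.03 log2, at 134 of 173 genes, whereas elav-nFne folds moved up by 0.41 ± 0.05, at 138 of 173 (both adjusted p = 1.3e-05, sign-flip permutation test).

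**Figure D4:**
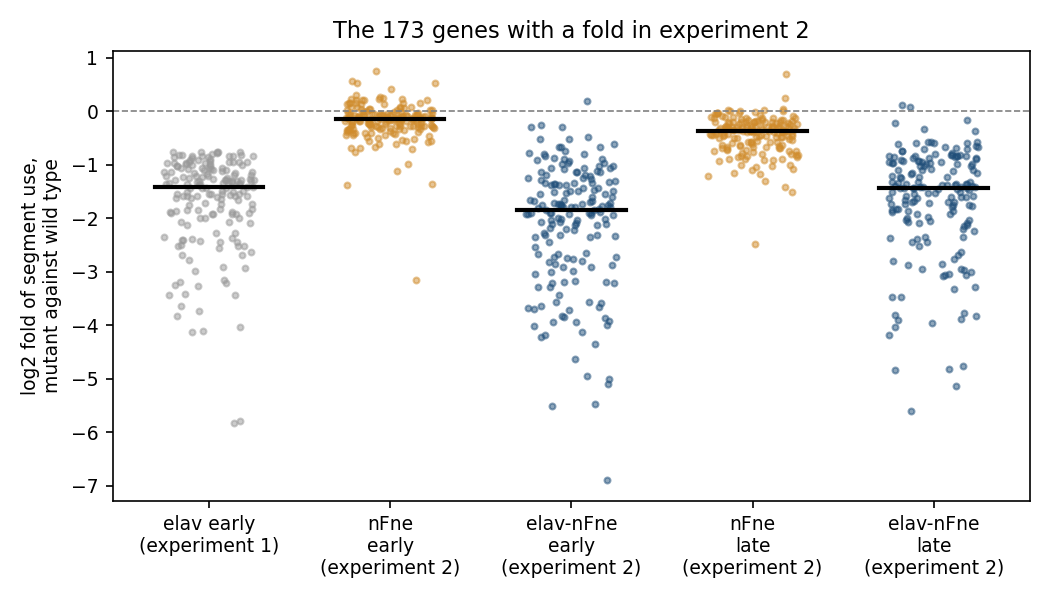
Authors' log2 fold of segment use (vertical axis) at 173 genes, 1 point per gene and a bar at the median, in elav early embryos of the first experiment and in the 4 comparisons of the second. The elav values were all selected to be -0.75 or lower. Medians were -0.15 and -0.37 in nFne and -1.84 and -1.43 in elav-nFne.

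Genes for RNA-binding proteins and transcription factors were over-represented in each list of a mutant that lacks elav, and channel and guidance genes in each of those lists except elav late. Of 34 RNA-binding and post-transcriptional regulators in the background, 15 fell in elav early (odds ratio 57.7, adjusted p = 7.1e-18) and 19 in elav-fne early (odds ratio 72.6, adjusted p = 1.3e-22), by Fisher's exact test over 140 tests. The 15 include elav and fne, the 19 also Rbp9, and 7 and 8 of them are in the ELAV family or in the literature list given below. Without the genes of those lists the odds ratios were 37.6 and 50.1 (adjusted p = 2.0e-08 and 8.8e-12, Fisher's exact test). The RNA-binding genes included shep (-2.45), bru3 (-1.83) and mei-P26 (-1.89) in elav, as log2 folds in the authors' deposited table. Transcription factors and chromatin genes gave 12 of 33 in elav early (odds ratio 41.0, adjusted p = 2.2e-13), among them abd-A (-2.98) and pros (-1.98) in the authors' deposited table. The ELAV family list, which holds the mutated genes, gave 2 of 3 in elav early and 3 of 3 in elav-fne early. Of 19 genes with known neuronal 3′ UTR extensions or ELAV-dependent processing, 12 fell in elav early and 14 in elav-fne early. That list was compiled from the literature on ELAV, so it is not independent of it. Axon guidance and adhesion genes gave 7 of 42 in elav and 10 of 42 in elav-fne (odds ratio 17.2, adjusted p = 2.8e-08), including Nrg (-3.84) and Dscam1 (-3.55) in the authors' deposited table for elav-fne. Ion channels gave 4 of 27 and 5 of 27, including Shal (-4.81) and slo (-7.12) in the same authors' deposited table. Their call in elav-fne-rbp9 was lost against genes with at least 2 segments marked as 3′ UTR (odds ratio 3.57, adjusted p = 0.097, Fisher's exact test). Synaptic genes numbered 3 of 26 in elav early and 8 of 26 in elav-fne-rbp9 (odds ratios 8.90 and 19.8, adjusted p = 0.017 and 4.4e-07, Fisher's exact test). For elav early this was lost against genes with at least 2 segments marked as 3′ UTR (odds ratio 4.20, adjusted p = 0.11, Fisher's exact test). Synaptic genes did not pass in elav-rbp9 (2 of 26, adjusted p = 0.089) or elav late (1 of 26, adjusted p = 0.28), by Fisher's exact test. Signalling genes gave 5, 6 and 8 of 26 in early elav, elav-fne and elav-fne-rbp9, and cytoskeleton genes 4, 5 and 4 of 20, each past an adjusted p of 0.05. Cytoskeleton genes did not pass in elav late (1 of 20, adjusted p = 0.23) or elav-fne late (2 of 20, adjusted p = 0.072), by Fisher's exact test. Late elav embryos listed 9 RNA-binding and 6 transcription factor genes (both past 0.05), with 0 of 27 ion channels and 1 of 42 axon guidance genes listed (adjusted p = 0.42 for the latter, Fisher's exact test). With elav intact, RNA-binding genes passed in fne early and fne-rbp9 (fne itself and sm in both, adjusted p = 0.027 and 0.013, Fisher's exact test), but not against genes with at least 2 segments marked as 3′ UTR (adjusted p = 0.13 and 0.073, Fisher's exact test). Nor did they pass without the ELAV family and literature lists, which left sm alone (adjusted p = 0.26 and 0.20, Fisher's exact test). Signalling genes passed in rbp9 early (dnc and rl, adjusted p = 0.00028) and fne-rbp9 (aPKC and rl, adjusted p = 0.0082), by the same exact test. Each of these calls rests on 2 genes, and rl is in both. The folds of rl were -6.56 in rbp9, -2.13 in fne-rbp9, -1.56 in elav-rbp9 and -2.02 in elav-fne-rbp9 in the authors' deposited tables. No list of a mutant with Rbp9 intact held rl. In all, 56 of the 140 tests passed. All listed genes have at least 2 segments marked as 3′ UTR, and against the 5046 such early and 5048 such late genes 49 of the 140 tests passed. Odds ratios were lower there: 23.7 and 30.1 for RNA-binding genes in elav and elav-fne early, 18.7 for transcription factors in elav early, 7.08 for guidance genes in elav-fne early and 9.83 for synaptic genes in elav-fne-rbp9.

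Few markers of other cell types were listed, but few would be by chance: the 4 marker lists had expected numbers of 0.0038 to 0.31 genes per list, so a shortage could not be seen. Glial and photoreceptor markers gave 0 listed genes in each of the 10 lists. Of 13 muscle markers only Mhc was listed, in elav-fne-rbp9 (-0.83 in the authors' deposited table, against 0.29 expected), and of 8 fat body markers only apolpp, in elav early (-1.10) and elav-fne early (-1.13) in the authors' deposited tables. The housekeeping gene eEF1alpha1 was in 6 lists, with folds from -0.81 to -1.60 in the authors' deposited tables. None of these 4 marker lists, nor the housekeeping list, passed an adjusted p of 0.05.

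Lists of different mutants and stages shared genes. Each of the 45 pairs of lists overlapped more than independent lists would (adjusted p under 0.05 in 45 of 45, Fisher's exact test). The gene SelR, listed in all 10, is part of every overlap. It was the only gene that rbp9 early shared with fne early, fne late and elav late (adjusted p = 0.028, 0.0041 and 0.034, Fisher's exact test). For elav and elav-fne early, 157 genes were shared against 3.44 expected, or 8.62 among genes with at least 2 segments marked as 3′ UTR. Against the latter genes, 43 of the 45 pairs passed. Pairs across stages, which share no wild-type library, gave 66 against 1.07 for elav early and late, and 143 against 3.20 for elav-fne (2.94 and 8.65 among genes with at least 2 segments marked as 3′ UTR). Both lists of each of these pairs set the same mutant genotype against wild type. A difference in genetic background would therefore recur at both stages, which was not tested. The X-linked genes CG43759, DIP1 and RhoGAP18B were listed in elav early, elav-rbp9 early and elav late. They were listed in elav-fne at neither stage, nor in elav-fne-rbp9. Most elav early genes, 157 of 185, were also in elav-fne early. Of all listed genes, 151 were in 1 list. SelR, which encodes a methionine sulfoxide reductase, was in all 10, fne in 9, and sm, an hnRNP gene, in 8. SelR folds ran from -0.84 in fne late to -1.98 in elav-fne-rbp9 in the authors' deposited tables, at a segment of 3R:10863887–10865626 with 89.9% of its bases in annotated 3′ UTR.

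Genes of 9 lists had more annotated sequence than other genes, and those of most lists were higher in wild-type adult heads. The summed segment length of genes in the elav early list was 4.15-fold that of other genes (median 8004 against 1760 bases), and that of the fne early list 2.32-fold (both adjusted p = 1.3e-05, permutation test). All listed genes have at least 2 segments marked as 3′ UTR, which by itself favours more annotated sequence. Length was not compared against such genes alone, so how much of the difference this makes is not known. The 6 rbp9 genes did not pass (1.89-fold, adjusted p = 0.054, permutation test). For the last segment alone, the elav early difference was 1.05 log2, against 2.05 for all segments, and the fne early difference turned to -0.15 log2 and did not pass (adjusted p = 0.60, permutation test). In heads, Rbp9 stood at 88.1 ± 3.8 TPM (SD, n = 2), fne at 24.8 ± 0.64 and elav at 13.4 ± 0.06. The 2 head replicates had Pearson's r of 0.997 and Spearman's rho of 0.980 across 17753 genes, which are not independent. Genes listed in elav early were higher than other genes by 1.92 on the log2(TPM + 1) scale, and those in fne early by 2.26 (both adjusted p = 1.3e-05, permutation test). Against other genes with at least 2 segments marked as 3′ UTR the differences were 1.03 and 1.37, among genes at 1 TPM or more 0.68 and 1.11, and with a pseudocount of 10 they were 0.89 and 1.14. The 8 fne late genes did not differ detectably (0.67, adjusted p = 0.41, permutation test), nor did the 6 rbp9 genes (1.69, adjusted p = 0.074, permutation test). Abundant head transcripts of cell types that gave few or no listed genes included ninaE (rhodopsin, 7804 ± 221 TPM), Act57B (1882 ± 238), Gs2 (719 ± 134) and Lsp2 (141 ± 40), each SD with n = 2. These are adult values. Abundance in the embryos behind the lists was not available, so absence from a list cannot be read against adult abundance. Neuronal genes stood at 502 ± 10 TPM for Fas1, 293 ± 4.0 for nSyb, 140 ± 15 for nAChRbeta1 and 175 ± 6.8 for unc-104 (SD, n = 2).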

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

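The test of single genes and the test at 1e-20 in the second paragraph were set before their results were seen; the tests of selection over all elav genes, of precision, of a weaker late dependence, of FNE acting without ELAV and of the triple mutant were chosen after related values were seen. The results here stood out because the effect of the same mutant differed between early and late embryos. Late minus early log2 folds were 0.55 for elav, 0.66 for elav-fne and 0.41 for elav-nFne, all toward 0, but -0.26 for nFne, away from 0, each past the test of the difference. Lower precision of the late libraries could shorten the late lists: the dispersion at genes listed at both stages was 2.72 times higher late in elav and 2.20 times in elav-fne. Precision alone does not move folds, yet at identical segments they were nearer 0 late by 0.51 in elav (29 genes, p = 0.0024) and 0.44 in elav-fne (67 genes, p = 1e-05, sign-flip permutation tests), so it is not the whole cause. A weaker dependence on the mutated genes late is the hypothesis left open, with 0.41 over 173 genes in elav-nFne, whose libraries did not choose the genes. That genotype combines both mutations, so the 0.41 cannot be assigned to elav alone. In nFne alone the folds moved the other way (-0.26) at the same 173 genes. Those genes were chosen in early embryos, which by itself favours larger early effects, and the share of neurons at each stage was not tested.

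The decreases were larger in elav-fne than in elav. Selection on significance in both lists was argued against over all 185 elav genes: 69.2% of them (128) were lower in elav-fne at the same segment even with every other gene counted as not lower (p = 1.9e-07, exact binomial test), although choosing genes in elav favours larger elav folds. The difference of -1.68 at the 66 genes past 1e-20 in both decides nothing, because elav-fne had 0.54 times the counts and 1.33 times the dispersion of elav, so that a strict threshold itself asks for larger elav-fne folds. Part of the lower count may be the larger decrease itself, so the ratio does not measure depth alone. A few extreme genes or the mutated loci would leave the median at 0, but without elav and fne it was -0.69 over 155 genes (p = 1e-05, permutation test, the smallest it can give). FNE acting on the same segments when ELAV is absent may account for the pattern, since elav-nFne minus elav folds were -0.43 on average at 173 genes (134 lower, p = 1e-05, sign-flip permutation test), but that comparison confounds experiment with genotype and sets a weighted against an unweighted fold.

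The triple mutant listed 103 genes that elav-fne did not. The same kind of change, short of the threshold in elav-fne, would give the same kinds of segment, but segments marked as the first of the 3′ UTR were more frequent, with an odds ratio of 7.95, and segments coded TE were less frequent (45.6% against 78.5%, p = 2.8e-08, Fisher's exact test). A higher count depth (median count ratio to elav-fne 1.67 at the 181 shared genes) would add genes like those just past the threshold in elav-fne, but against the 59 genes of that list nearest the threshold, first segments were again more frequent (34.0% against 5.08%, odds ratio 9.61, p = 1.3e-05, Fisher's exact test), so depth is not the whole cause, although it may add some of the genes. A role of Rbp9, or of embryo condition or developmental delay in the triple mutant, stays open and was not tested.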

How the results depend on the processing

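The settings with an adjusted p under 1e-10, 3′ UTR segment backgrounds, summed 3′ UTR segment length, and the removal of elav and fne or of the ELAV family and literature list were chosen after seeing the data. Of all results under all alternatives, 412 kept their direction and side of the threshold, or stayed within 1.5 times the count, 19 moved, 11 weakened, 1 strengthened and 6 reversed. The fold limit of 1 left 38 genes in fne early, and 3 (nFne early) and 9 (nFne late) of the fixed genes. Under 1e-10 the lists held 11 (fne), 9 (fne-rbp9), 92 (elav-rbp9), 167 (elav-fne-rbp9), 5 (fne late) and 34 (elav late), and the fixed genes past it were 2 (nFne early), 66 (elav-nFne early), 3 (nFne late) and 93 (elav-nFne late). At 0.001, 3 genes passed in nFne early and 5 in nFne late, and at 0.01, 14 in nFne late. With the fold limit, 100% of nFne early folds were lower, but the 4 genes left cannot pass. The median difference of elav-rbp9 and elav was 0.053, short of the threshold. That of fne-rbp9 and fne was 0.16 as a median and 0.066 without fne itself, both reversed because fne dominates the mean. Against genes with 2 or more 3′ UTR segments, odds ratios of 4.20 (synaptic genes, elav early), 3.57 (ion channels, elav-fne-rbp9) and 5.71 and 8.68 (RNA-binding genes, fne early and fne-rbp9) no longer passed, nor did 9.51 (fne early) against genes at 1 TPM or more in heads, nor 9.72 and 14.7 (RNA-binding genes, fne early and fne-rbp9) without the ELAV family and literature list, where fewer members remain. Head expression of fne late genes reversed to -0.15 at 1 TPM or more and -0.28 against genes with 2 or more 3′ UTR segments. The head replicates' Pearson's r was 0.995, 0.996 and 0.991 with pseudocounts of 0.1 and 10 and at 1 TPM or more. For the last segment only, log2 length differences were -0.19 (rbp9) and -0.15 (fne), reversed, and 0.064 (fne-rbp9) and 0.26 (fne late), weaker. With summed 3′ UTR segments rbp9 reached 1.498 and passed. Except where stated, the cause was not tested. All 45 overlaps held at each planned background, 43 against genes with 2 or more 3′ UTR segments and 40 with the fold limit. Thresholds of 0.01 and 0.001 removed nothing from the 10 lists, and any-segment backgrounds added at most 1 gene, so those settings test nothing. Counting segments in place of genes gave 7 (rbp9) to 362 (elav-fne-rbp9), within 1.5 times each gene count. For the direction of change, taking the largest change per gene gave no value, because tables hold 1 entry per gene. No paired analysis was possible because the comparison tables carry no replicate columns and the heads form 1 group, and edgeR-type, replicate-block and leave-one-out fits of the embryos were not run for the same reason. Leaving out either head replicate changed no call. Unknown embryo depth limits every absence from a list.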

Other observations

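The tests in this part were chosen after the data were seen. The X chromosome, which carries elav and fne, held more of 5 lists than its share of annotated genes (16.0%). That share is over all annotated genes, and the lists were not tested against genes with at least 2 segments marked as 3′ UTR. It held 25.1% of the elav-fne early list (59 of 235, adjusted p = 0.0030), 23.2% of elav early (43 of 185, adjusted p = 0.037) and 5 of the 8 fne late genes (adjusted p = 0.019), and the elav-rbp9 and elav-fne late lists also passed (both adjusted p = 0.042), by Fisher's exact test. The other 5 lists did not pass, among them fne early (25.9%, adjusted p = 0.080) and elav-fne-rbp9 (19.0%, adjusted p = 0.23), by the same exact test. These counts include the mutated genes and hec, the neighbour of fne. Without elav, fne and hec only elav-fne early passed (57 of 233 genes, adjusted p = 0.0078), while elav early (41 of 183, adjusted p = 0.12) and fne late (3 of 6, adjusted p = 0.14) did not, nor did the other 7 lists, by the same exact test.

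Across the 173 fixed genes, early elav-nFne folds and elav folds of the first experiment had Pearson's r of 0.64 and Spearman's rho of 0.65, across genes that are not independent. At the 148 of these genes also listed in elav-fne, elav-nFne folds were nearer 0 than those of elav-fne by a mean of 0.73 log2, and only 41 were lower, in tables fitted separately. Being listed in elav-fne by itself favours larger elav-fne folds, and the mean includes the elav-fne model fits near 0 at fne and Sxl. The comparison also confounds experiment with genotype and sets a weighted against an unweighted fold.

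HIP-R shows a limit of the weighted folds. In the authors' deposited tables its adjusted p was 4.3e-19 in nFne early and 9.9e-13 in nFne late with folds of 0.03 and 0.02, whereas elav early of the first experiment gave -0.95. The gene chic went the other way, with -0.83 in elav early and -3.15 in nFne early in the authors' deposited tables. It was not listed in fne early or fne late. SelR, the gene in all 10 lists, was 1 of 11 genes of the elav early list outside the second experiment.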
